A study of Homo sapiens with 6 samples.

How the data were processed

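Total RNA of KASUMI-3, a human acute myeloid leukaemia cell line, was labelled with a single dye (Cy3) and hybridized to 6 Agilent arrays, all on 1 slide. The labels name 3 groups of 2 arrays each, cells with a scrambled control hairpin, cells with a first shRNA against HAVCR2 (shRNA 1) and cells with a second (shRNA 2). Per the labels all cells were kept in puromycin. The scramble arrays lay in row 1 of the slide, columns 1 and 2, the shRNA 1 arrays in row 1, columns 3 and 4, and the shRNA 2 arrays in row 2, columns 3 and 4. Position on the slide and group therefore cannot be told apart.

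Per the file headers, the authors' scanner files hold signal intensity, the background-subtracted and detrended Cy3 signal of each spot, written by Agilent Feature Extraction version 11.5.1.1 with no normalization between arrays. The same deposited files hold the raw median intensity of each spot and of its local background, and flags for spots well above background, saturated spots and outlier spots. The authors also deposited a value table on the log2 scale. The labels do not state how it was made. Its differences between arrays match log2 signal minus each array's 75th percentile over all probes, after which each probe was centred on its median over the 6 arrays. That table was used as an alternative only.

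From the scanner files, spots were averaged per probe on the log2 scale after outlier spots had been dropped. Of the 50599 probes other than controls, 50597 had a value on every array. Between 233 and 323 outlier spots were dropped per array, and no spot was saturated. Each array was scaled to its 75th percentile over the 17589 probes well above background on all 6 arrays, because only 40.6% to 48.6% of the spots were well above background on each array. Taking the percentile over all probes is an alternative added after the data were seen. A probe was kept if it was well above background on both arrays of at least 1 group, which left 21595 probes. Probes were named through the RefSeq accessions in the array annotation and a table of human gene symbols (assembly GRCh38.p14). The array header names another build, hg19, so no coordinates are given. Of the 25219 probes with an NM accession, 24546 matched a gene, 28173 probes had a single symbol and 22424 had none. Probes without a symbol kept the name in the annotation. The probe with the highest mean signal over all arrays stood for its gene, which gave 17367 genes tested.

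The test was limma 3.58.1 in R 4.3.3, with all 6 arrays in a fit of 3 groups and moderated variances, 3 residual and 1.62 prior degrees of freedom. The contrasts were the mean of both shRNA groups against scramble (called the shRNA mean), each shRNA against scramble, and shRNA 2 against shRNA 1. P-values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. The number of arrays, 2 per group, limits the precision. Errors of fold changes are limma's standard errors (SE) and errors of group means are standard deviations (SD). Where the dimmer group had no array well above background, the fold is a lower bound, written "at least", for which signals under the lowest signal called well above background on that array were raised to it. Fold changes of both shRNAs share their controls, so the correlation and the covariance are given beside 50 simulations of unchanged groups that shared 2 controls. With 2 control arrays a split would leave 1 on each side, so no split was made.

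There were 41 gene lists, written before the data were examined, as were the contrasts, the thresholds, the rule for named genes and the alternatives. They cover TIM-3 partners, the TIM gene family, Wnt targets and components, NF-kB targets, ERK output, FOXO and STAT5 targets, the 17 genes of the leukaemic stem cell score LSC17, stem and progenitor genes, markers of 9 cell types, MHC classes, interferon response, cell cycle, histones, MYC and ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, hypoxia and glycolysis, cholesterol synthesis, ATF4, unfolded protein and heat shock responses, p53 targets, BCL2 family, immediate early genes, chemokines, cytokines and receptors, immune checkpoints, Src kinases, integrins, and the small RNA machinery. Lists with at least 5 measured members, 40 of the 41, were tested with camera at a preset correlation between genes of 0.01, adjusted over lists. Camera with an estimated correlation and fry (limma's rotation test) were run beside it. The first takes its p from only 3 degrees of freedom, against many more at the preset correlation, so few lists can pass it. Fry asks whether a list moved at all, not whether it moved more than other genes.

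The rule for named genes took HAVCR2 and the measured members of the lists TIM-3 partners and TIM gene family, and the 12 highest and 12 lowest fold changes of the shRNA mean among genes that also passed with each shRNA in the same direction. It further took the 6 highest and 6 lowest differences between shRNA 2 and shRNA 1, and the 4 members of each list with the smallest p. Highest and lowest genes had to carry a gene symbol and to be well above background on both arrays of the higher group, and XIST and Y-linked genes were left out. At most 30 of the list members that the rule chose are printed with values, and not every gene that the rule took is named. Other members are named where the counts of a list call for them, and these were chosen after their values were seen.

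Alternatives were quantile normalization, centring on the median, a normexp background correction, other filters on dim probes, other forms of moderation, fits on the compared arrays only, other ways to treat several probes of a gene, the authors' value table, the replicate number as a block, stricter thresholds and leaving out each array. The planned normexp correction named a mean signal column that the files lack, so it was run on the median signal with an offset of 50, a choice made after the data were seen. The offset was added before scaling, so by construction it pushes dim probes upward on dimmer arrays, here those of both shRNA groups. A fit without both arrays labelled shRNA 2 was also added after the data were seen. A block for slide or scan was not run, since there was 1 of each. The fit and the list test were tried on simulated data for 17367 genes. Dropping of outlier spots, scaling, the filter on dim probes, the choice of probe and the bounds were not simulated. For the shRNA mean the fit recovered 38% of planted changes of 0.5 on the log2 scale, 80% of changes of 1, 96% of changes of 2 and 100% of changes of 4, with 21 false calls. For shRNA 2 against shRNA 1 the shares were 10%, 90%, 90% and 100%. The 1 planted list was recovered and no other list was called. The run was set to stop unless the planted list passed, so its recovery is only a check of the code. Noise was drawn independently for each gene, whereas the estimated correlation within the ribosomal protein list was 0.32. The simulation therefore cannot show how often lists of correlated genes are called falsely. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. TIM-3 protein was not analysed here.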

Results

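KASUMI-3 is a line of human acute myeloid leukaemia cells that carry TIM-3, the surface receptor encoded by HAVCR2. Transcript levels were measured on 6 arrays, 2 of cells with a scrambled control hairpin, 2 of cells with shRNA 1 against HAVCR2 and 2 of cells with shRNA 2. The series asks what TIM-3 signalling does in these cells. The share of spots well above background was 48.6% and 45.3% on the scramble arrays, 43.3% and 43.2% on the shRNA 1 arrays, and 42.9% and 40.6% on the shRNA 2 arrays. The scramble arrays were also the brightest, with raw 75th percentiles of 822 and 680 against 519 and 527 with shRNA 1 and 538 and 413 with shRNA 2. Over the 17367 genes tested, the arrays of a group differed with an SD on the log2 scale of 0.271 for scramble, 0.319 for shRNA 1 and 0.369 for shRNA 2. The mean of the scramble arrays differed from that of the shRNA 1 arrays with an SD of 0.911 and from that of the shRNA 2 arrays with an SD of 0.863, and the shRNA means differed from each other with an SD of 0.598. The labels call the arrays of a group duplicates and do not say whether they came from separate cultures, so every p-value measures only the spread between arrays, which may be technical.

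HAVCR2, the target of both shRNAs, was lower on the shRNA 1 arrays and was not lower on the arrays labelled shRNA 2. Relative to each array's 75th percentile, its log2 signal on its 1 probe (A_24_P411561) was -2.53 and -2.33 on the scramble arrays, -4.00 and -4.07 on the shRNA 1 arrays, and -2.28 and -2.20 on the arrays labelled shRNA 2. With shRNA 1 it was 3.04-fold lower than in scramble (log2 fold change -1.61 ± 0.09 SE, n = 2 arrays per group, adjusted p = 0.000501 by limma). On the arrays labelled shRNA 2 the log2 fold change was 0.19 ± 0.09 (adjusted p = 0.155), and the difference between the shRNAs was 1.79 (adjusted p = 0.00141). The shRNA mean, -0.71 ± 0.08 (adjusted p = 0.00239), thus rested on the shRNA 1 arrays, and because of this the groups are named as their labels name them, with "the arrays labelled shRNA 2" for the second. After a normexp background correction HAVCR2 fell by 0.61 on the log2 scale with shRNA 1 and was 0.30 higher on the arrays labelled shRNA 2, past the threshold (adjusted p = 0.041), and the shRNA mean no longer passed (adjusted p = 0.173). The offset of this correction lifts dim probes on the dimmer shRNA arrays, so these shifts may not reflect HAVCR2 itself. With the 4 shRNA arrays taken as 1 group, which puts the difference between the shRNAs into the spread, the shRNA mean of HAVCR2 did not pass either (adjusted p = 0.444).

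Among the genes of TIM-3's ligands and partners, 2 rose in the shRNA mean and HAVCR2 itself fell. PLCG2, a phospholipase that acts under immune receptors, rose 3.12-fold (log2 fold change 1.64 ± 0.09, adjusted p = 0.000357). LGALS9, which encodes the TIM-3 ligand galectin-9, rose 1.84-fold (0.88 ± 0.09, adjusted p = 0.00204), by 0.57 with shRNA 1 and by 1.18 on the arrays labelled shRNA 2. The other 7 of the 10 measured partners did not pass, with log2 fold changes that included 0.16 for the catenin gene CTNND1, 0.13 for CEACAM1, -0.08 for LCP2, -0.11 for LYN, -0.13 for HMGB1 and -0.15 for the Wnt co-receptor gene LRP6. The other kept probe of CEACAM1 read -0.35. CTNND1 and CEACAM1 passed after centring on the median (adjusted p = 0.0416 and 0.0377), LYN and HMGB1 after quantile normalization (adjusted p = 0.0176 and 0.0359), and LYN after normexp (adjusted p = 0.0370). Without both arrays labelled shRNA 2, LCP2 (-0.28, adjusted p = 0.0331) and LYN (-0.29, adjusted p = 0.0420) passed. Adjusted over the list alone, 2 partners rose and 1 fell as well, and the list as a whole did not pass camera (adjusted p = 0.587). By group, it did not pass with shRNA 1 (2 higher and 2 lower, adjusted p = 0.504) and passed on the arrays labelled shRNA 2 (5 higher and 0 lower, adjusted p = 0.0284, adjusted p = 0.272 with an estimated correlation). In the TIM gene family, HAVCR1 had a log2 fold change of 0.13 (adjusted p = 0.652, and 0.00197 after normexp), and the family was too small to test. BAG6, FYN, LCK and TIMD4 were not among the genes tested. Their probes were either not well above background or not matched to the symbol, so this does not show that the genes were silent.

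**Figure D1:**
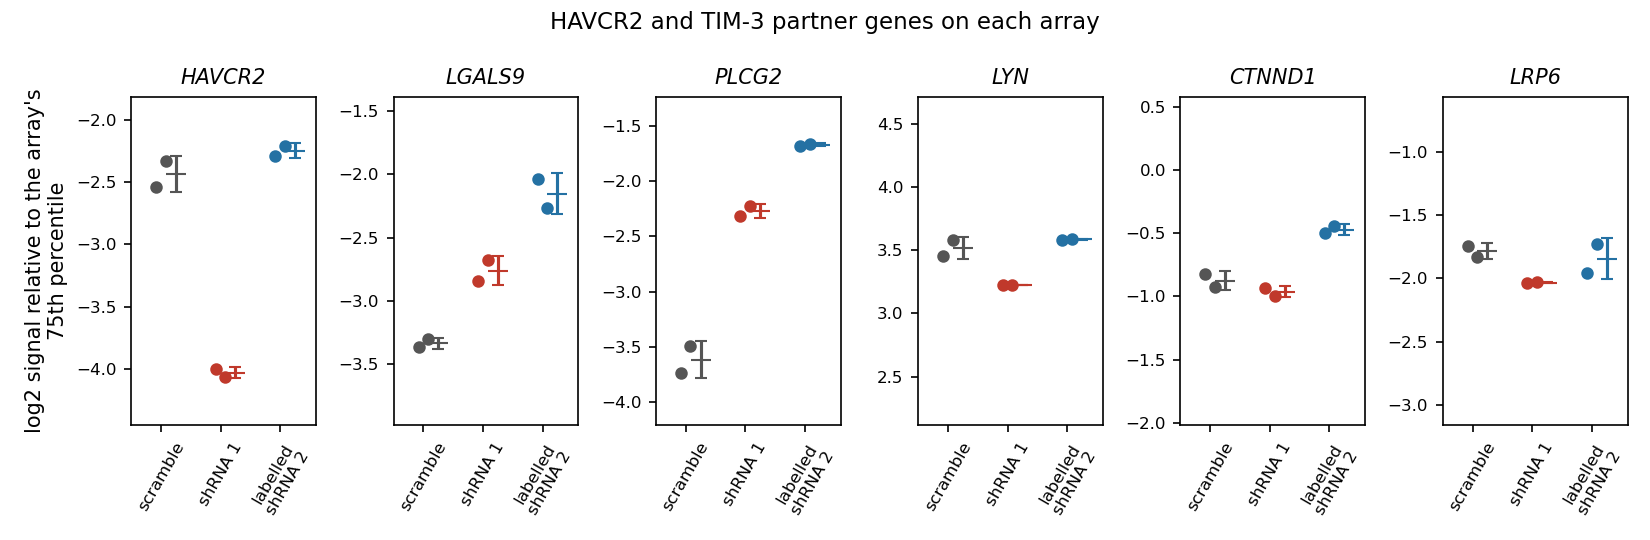
Log2 signal relative to the array's 75th percentile of HAVCR2 and 5 partner genes on each array (dots), with the group mean and SD (bars, n = 2). HAVCR2 lay at -4.00 and -4.07 on the shRNA 1 arrays and at -2.28 and -2.20 on the arrays labelled shRNA 2, while PLCG2 was higher than in scramble on all 4 shRNA arrays.

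Against scramble, both shRNA groups had far higher levels of inflammatory cytokine and chemokine transcripts, of immediate early transcription factors, and of several genes of mature blood cells. IL1B, which encodes interleukin-1 beta, was at least 90.5-fold higher (log2 fold change 8.35 ± 0.10, adjusted p = 3.65e-05), CXCL1 was 117-fold higher (6.87 ± 0.08) and CCL4 was 65.9-fold higher (6.04 ± 0.07). RGS16, a regulator of G-protein signalling, was at least 135-fold higher, the chemokine gene CCL1 at least 20.3-fold, and IL1RL1, which encodes the interleukin-33 receptor, at least 18.8-fold. EGR1 rose 42.7-fold (5.42 ± 0.07) and NR4A1 at least 21.9-fold, both immediate early transcription factors. The beta-globin gene HBB rose at least 35.2-fold, the myeloperoxidase gene MPO at least 15.7-fold, SELP, which encodes the platelet adhesion protein P-selectin, at least 53.6-fold, and the neurofilament gene NEFM at least 11.2-fold.

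The lowest fold changes included WFDC21P, which fell 31.5-fold (-4.98 ± 0.08, adjusted p = 4.41e-05), and GABBR2, which encodes a subunit of the GABA-B receptor and fell 15.7-fold (-3.97 ± 0.06). The phospholipase D gene PLD2 fell by 3.46 ± 0.16 on the log2 scale, UTP14A 10.8-fold (-3.44 ± 0.27) and HSDL2 10.6-fold (-3.40 ± 0.16). FAM177B was at least 11.7-fold lower, MS4A4A at least 11-fold, TMEM61 at least 10.1-fold, ETNPPL at least 9.90-fold, LPAR3 at least 5.01-fold and GSTM2P1 at least 2.45-fold. In total 9705 of 17367 genes passed (55.9%), 4429 higher and 5276 lower, and 10807 had an unadjusted p under 0.05. Of these, 1099 were higher and 1240 lower by 2-fold or more. The balance of higher and lower genes depended on the scaling, with 45.6% of the calls higher as scaled here, 51.5% after centring on the median and 73.0% after normexp, which moved the median of all genes by 0.30 on the log2 scale. The normexp offset, added to every signal before scaling, lifts dim probes on dimmer arrays, here the shRNA arrays. The share of 73.0% is therefore at least partly by construction. Normexp also shrank the folds of dim genes, such as IL1B to 3.58 and FAM177B to -1.14, and GSTM2P1 no longer passed (adjusted p = 0.462). With the 4 shRNA arrays taken as 1 group, 5098 genes passed and GABBR2 did not (adjusted p = 0.117).

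**Figure D2:**
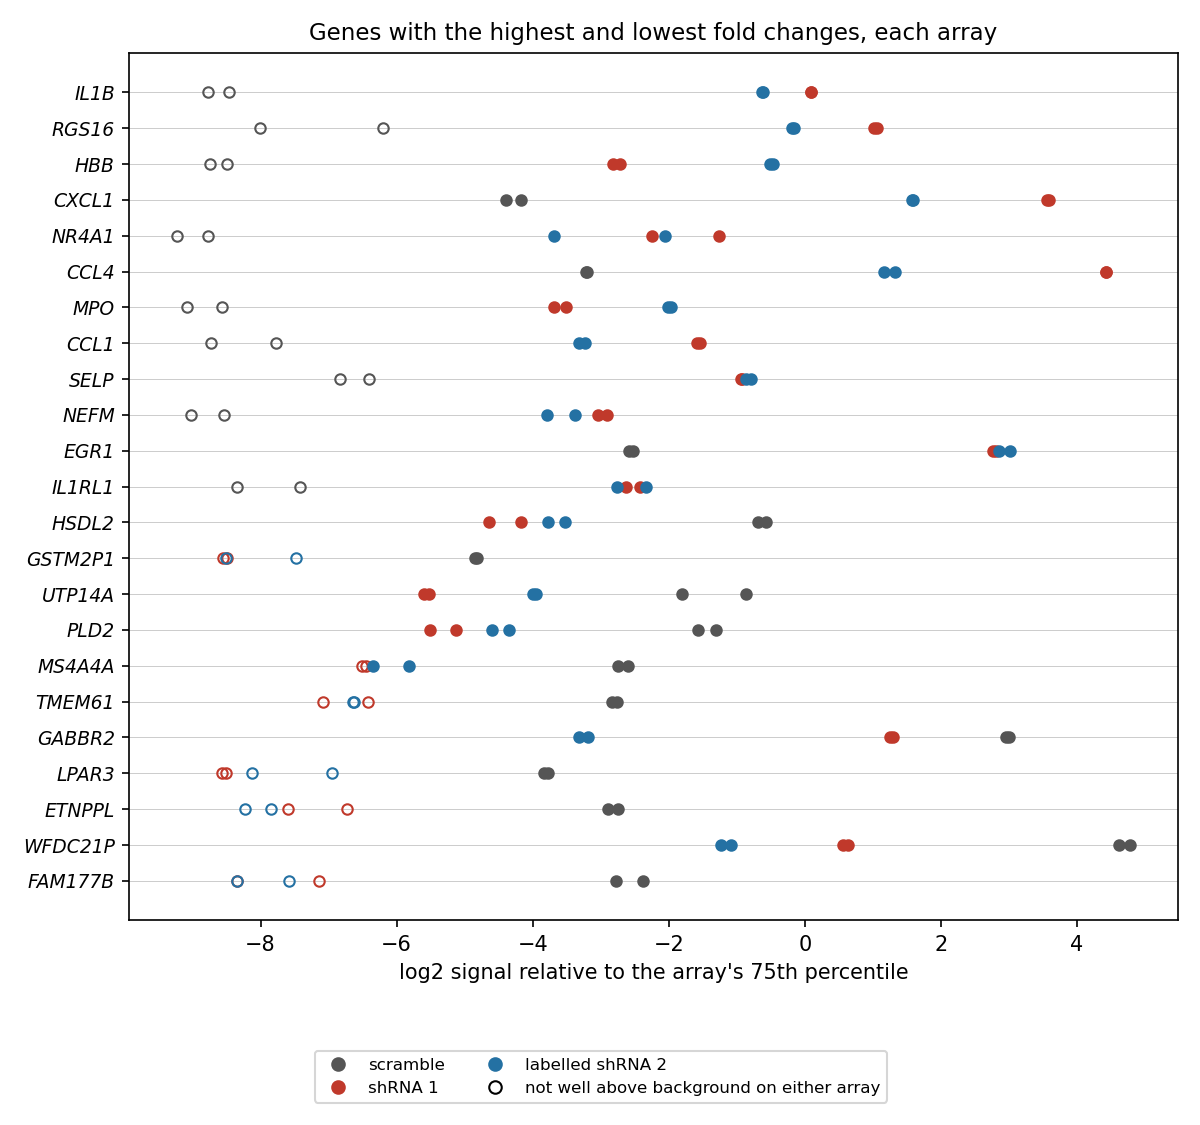
Log2 signal relative to the array's 75th percentile of the 12 genes with the highest and 11 of the 12 with the lowest fold changes of the shRNA mean, 1 dot per array. Open dots mark groups in which no array was well above background. In every gene the 4 shRNA arrays lay on the same side of both scramble arrays, which the rule that chose these genes nearly fixes.

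Each shRNA group was far from scramble, and mostly in the same direction, although HAVCR2 itself was lower only with shRNA 1. IL1B was at least 116-fold higher with shRNA 1 and at least 70.4-fold on the arrays labelled shRNA 2, EGR1 40.6-fold and 45.0-fold, and LEF1, a transcription factor of the Wnt pathway, was 4.27-fold and 3.23-fold lower. With shRNA 1, 9051 genes passed, 4224 higher and 4827 lower. On the arrays labelled shRNA 2, 9248 genes passed, 4303 higher and 4945 lower. Both groups had passed in the same direction for 6004 genes, 2886 higher and 3118 lower, and in opposite directions for 460. The balance of these genes turned with the scaling, with 3368 higher and 2560 lower in the authors' value table and 4764 and 1797 after normexp. Independent lists of these sizes would share 2421 genes in direction. Across genes, which are not independent replicates, the fold changes correlated with a Pearson r of 0.774 and a Spearman rho of 0.706, against means of 0.499 and 0.454 for unchanged groups simulated against the same 2 controls. Their covariance was 0.608 against 0.0184, so array noise shared through the controls explained little of it. The simulated r comes from groups that vary by noise alone, and is not a share of the observed r. A difference of the scramble cells themselves would also be shared by both fold changes, and was not simulated.

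**Figure D3:**
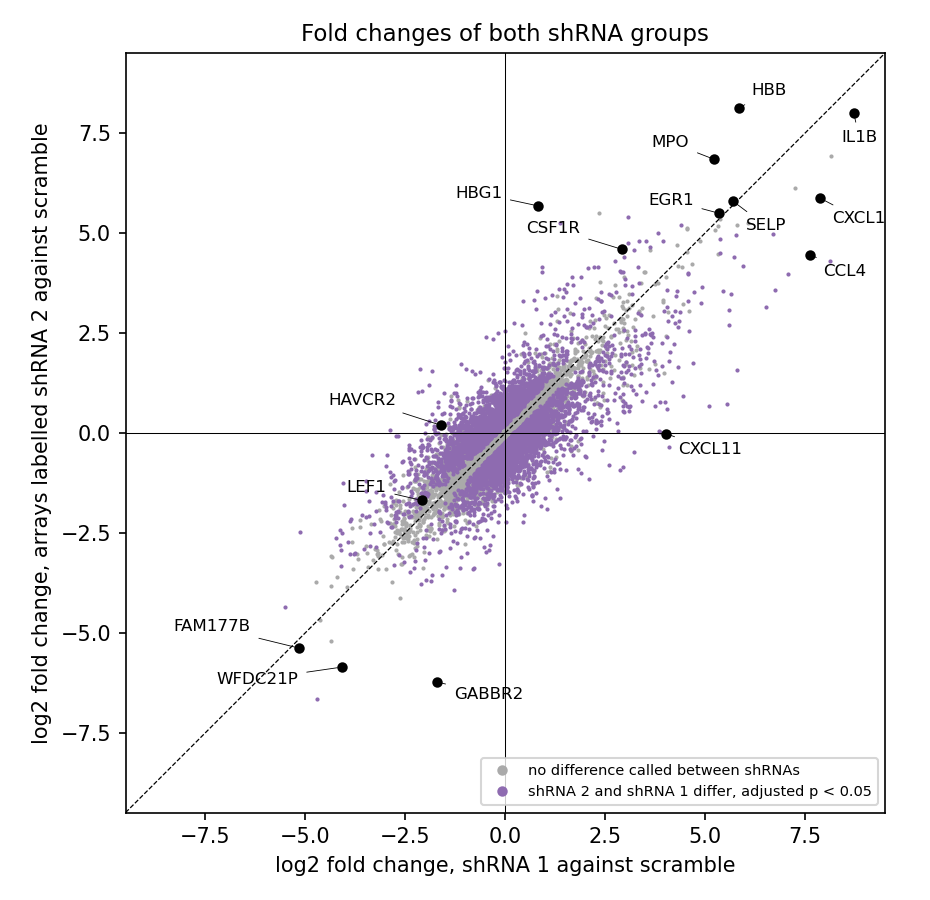
Log2 fold change against scramble of each gene, with shRNA 1 on the horizontal and the arrays labelled shRNA 2 on the vertical axis, and the line of equality dashed. Purple dots mark the 6385 genes that differed between the shRNAs, black dots are named genes, and HAVCR2 lies at -1.61 and 0.19.

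Genes driven by NF-kB, an inflammatory transcription factor, rose almost as a block. Of 26 measured NF-kB targets, 24 rose, 1 fell and 1 did not pass, with a median log2 fold change of 2.88 (camera adjusted p = 2.57e-13, adjusted p = 0.141 with an estimated correlation). CXCL3 rose by 5.05 and TNF by 3.92 on the log2 scale, the kinase gene MAP3K8 fell, past the threshold except after normexp (adjusted p = 0.104), and the survival gene BCL2A1 read -0.13 on its brightest probe and 5.44 on its other probe. Of 20 immediate early genes, 18 rose, 1 fell and 1 did not pass, with a median of 3.00 (adjusted p = 6.78e-11, adjusted p = 0.141 with an estimated correlation). FOSB rose by 5.24, KLF2 rose too, and JUN fell. The fall of JUN did not pass with the 4 shRNA arrays as 1 group (adjusted p = 0.153) or without both arrays labelled shRNA 2 (-0.20, adjusted p = 0.0923). Of 34 chemokine, cytokine and receptor genes, 22 rose and 6 fell, with a median of 1.15 (adjusted p = 4.44e-06, adjusted p = 0.141 with an estimated correlation). Of 9 genes of ERK output, 6 rose and 1 fell, with a median of 1.26 (adjusted p = 0.00854, adjusted p = 0.396 with an estimated correlation). SPRY1, a feedback inhibitor of the pathway, rose by 2.24, and the gene that fell was MYC, by 0.97 on the log2 scale. The ERK list did not pass without both arrays labelled shRNA 2 (adjusted p = 0.0626) or after normexp (adjusted p = 0.0596, median 0.74), and normexp left the chemokine list a median of 0.64. Adjusted over the list alone, these 4 lists gave the same counts.

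Among the markers measured, those of several mature blood lineages rose together. A marker undetected in scramble was measured only if detected with an shRNA, and markers undetected in every group dropped out. Shares of measured genes are thus above those of all markers. Of those on the array, 10 of 24 monocyte, 8 of 20 granulocyte, 8 of 20 megakaryocyte and 7 of 17 mast cell, basophil and eosinophil genes rose. Of 16 measured monocyte genes, 10 rose and 3 fell, with a median log2 fold change of 1.44 (adjusted p = 0.00482, adjusted p = 0.335 with an estimated correlation). CSF1R, which encodes the receptor of macrophage colony-stimulating factor, rose by 3.76 and S100A8 by 3.52, while CD14 fell. Over probes well above background on all 6 arrays only, the monocyte list did not pass (adjusted p = 0.478). After normexp the median was 0.63 for monocyte genes, 0.76 for granulocyte genes and 0.62 for mast cell, basophil and eosinophil genes, against 0.22 for all genes. Of 11 granulocyte genes, 8 rose and 2 fell, with a median of 1.28 (adjusted p = 0.00379, adjusted p = 0.335 with an estimated correlation), among them the transcription factor gene CEBPA, which rose by 2.13 but did not pass with the 4 shRNA arrays as 1 group (adjusted p = 0.0521). Of 9 mast cell, basophil and eosinophil genes, 7 rose and 1 fell, with a median of 1.26 (adjusted p = 0.00854, adjusted p = 0.335 with an estimated correlation), led by HDC, which makes histamine and rose by 5.11. Of 14 megakaryocyte genes, 8 rose and 4 fell, with a median of 1.25 (adjusted p = 0.0247, adjusted p = 0.335 with an estimated correlation). The integrin gene ITGB3 rose by 3.16, THBS1 fell, and over probes well above background on all 6 arrays the list did not pass (adjusted p = 0.571). Nor did it pass after normexp (adjusted p = 0.0766), with the percentile over all probes (0.0509), with camera on ranks (0.0775) or without both arrays labelled shRNA 2 (0.0508).

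Of 10 erythroid genes, 4 rose and 2 fell, and the list did not pass (adjusted p = 0.689), with a median of -0.04, or 0.22 after normexp, and a mean of 1.05. GATA1, a transcription factor of red cells and platelets, was at least 7.59-fold higher, and the glycophorin gene GYPE fell. HBB was well above background on 4 shRNA arrays and the alpha-globin gene HBA2 on 0. Lists of other cell types did not pass, with 3 genes higher and 3 lower of 8 T and NK cell genes (adjusted p = 0.587), 2 and 2 of 7 B cell genes (adjusted p = 0.716), 1 and 2 of 7 fibroblast and endothelial genes (adjusted p = 0.587), and 1 and 1 of 5 epithelial genes (adjusted p = 0.633). The B cell transcription factor gene EBF1 rose. Adjusted over the list alone, 3 T and NK cell genes rose and 4 fell and 2 B cell genes rose and 4 fell, and the other 7 cell type lists gave the same counts.

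Stem cell, Wnt and growth factor response genes moved both ways and their lists did not pass. Of 33 stem and progenitor genes, 10 rose and 17 fell (adjusted p = 0.285), with a median of -0.61, or -0.28 with dim genes at their bound and -0.18 after normexp. The homeobox gene HOXA3 fell by 2.48 on the log2 scale and HOXA5 fell too, while LMO2 rose 6.07-fold. Adjusted over the list alone, 11 rose and 17 fell. Of the 17 genes of the LSC17 score, 6 rose and 7 fell (adjusted p = 0.736), among them CPXM1, which rose by 2.06, and CD34, which fell by 0.61 on the log2 scale. CD34 did not pass with the 4 shRNA arrays as 1 group (adjusted p = 0.180). Of 12 Wnt targets, 3 rose and 7 fell, or 8 adjusted over the list alone (adjusted p = 0.199), with a median of -0.51, or -0.42 with dim genes at their bound and -0.05 after normexp. LEF1 fell by 1.89 on the log2 scale and VEGFA rose. Of 27 Wnt components, 7 rose and 8 fell (adjusted p = 0.716), with log2 fold changes of 0.59 for CTNNB1, which encodes beta-catenin, and -0.65 for the kinase gene CSNK1A1, both past the threshold. Of 17 FOXO targets, 7 rose and 6 fell (adjusted p = 0.346). Of 13 STAT5 targets, 4 rose and 7 fell (adjusted p = 0.699), with a median of -0.20 and a mean of 0.16. OSM rose and SOCS3 fell among these. The LSC17, Wnt component, FOXO and STAT5 lists gave the same counts adjusted over the list alone.

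Genes of translation and chromatin moved as groups of small steps. Of 35 ribosomal protein genes, 34 rose and 0 fell, with a median log2 fold change of 0.56 (adjusted p = 7.33e-10, adjusted p = 0.355 with an estimated correlation), and 35 rose adjusted over the list alone. RPL15 rose by 1.14 on its brightest probe, while its other probe read -0.66. After quantile normalization the list's median was 0.16, and these genes were among the brightest on the array. Of 33 genes of MYC and ribosome biogenesis, 22 fell and 1 rose, with a median of -0.34 (adjusted p = 0.00107, adjusted p = 0.186 with an estimated correlation) and the same counts adjusted over the list alone. RRS1 fell by 1.34 on the log2 scale and FBL, which encodes the methyltransferase fibrillarin, rose by 0.75. Of 23 replication histone genes, 20 rose and 1 fell, with a median of 0.75 (adjusted p = 9.41e-07, adjusted p = 0.335 with an estimated correlation), and 21 and 1 adjusted over the list alone. H2AC4 rose by 1.19 and H2BC8 by 1.00.

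Of 33 G1/S genes, 16 rose and 8 fell, with a median of 0.14 (adjusted p = 0.0495, adjusted p = 0.533 with an estimated correlation) and the same counts adjusted over the list alone. MCM7, part of the replicative helicase, rose by 1.05 and the cyclin gene CCNE1 fell. The G1/S call ended without scramble replicate 1 (adjusted p = 0.0672), without either shRNA 1 array (0.0578 and 0.0506), without shRNA 2 replicate 1 (0.102) and with the replicate number as a block (0.0546). It also ended after quantile normalization (0.133), after normexp (0.827), with camera on ranks (0.0722), over probes well above background on all 6 arrays (0.116) and without both arrays labelled shRNA 2 (0.0651). Of 27 G2/M genes, 4 rose and 7 fell (adjusted p = 0.716), and 4 and 6 adjusted over the list alone. Of 33 genes of oxidative phosphorylation, 8 rose and 7 fell (adjusted p = 0.689), and 7 and 6 adjusted over the list alone, with a median of -0.03, or 0.05 in the authors' value table, and a mean of 0.02. Of 25 genes of hypoxia and glycolysis, 8 rose and 9 fell (adjusted p = 0.587), with a median of 0.11 and a mean of -0.04. NDRG1 and ADM rose, and the glycolysis genes ALDOC and HK2 fell.

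Of 23 cholesterol synthesis genes, 13 rose and 5 fell, with a median of 0.46 (adjusted p = 0.0422, adjusted p = 0.396 with an estimated correlation), and 13 and 6 adjusted over the list alone. INSIG1, which restrains cholesterol synthesis, rose by 1.44 (adjusted p = 0.0556 with the 4 shRNA arrays as 1 group). The call ended without shRNA 1 replicate 2 (adjusted p = 0.0538), without shRNA 2 replicate 1 (0.0680), without both arrays labelled shRNA 2 (0.264) and with the replicate number as a block (0.0546). It also ended after quantile normalization (0.0518), after normexp (0.317), with the percentile over all probes (0.0578) and with camera on ranks (0.0662). Of 25 genes of the ATF4 and amino acid response, 12 rose and 8 fell (adjusted p = 0.180), and 12 and 9 adjusted over the list alone, with ATF3 and DDIT4 among those that rose. Of 21 unfolded protein response genes, 5 rose and 8 fell (adjusted p = 0.764). Of 15 heat shock genes, 5 rose, HSPA1A among them, and 2 fell (adjusted p = 0.220). Of 23 p53 targets, 11 rose and 4 fell (adjusted p = 0.0668), with BBC3 higher and GADD45A lower. Of 18 genes of the BCL2 family list, 9 rose and 2 fell, with a median of 0.35 (adjusted p = 0.00482, adjusted p = 0.335 with an estimated correlation). The list was led by BIRC3, which rose by 3.22 and encodes an inhibitor of cell death outside the BCL2 family proper. After normexp the list did not pass (adjusted p = 0.111). The hypoxia, unfolded protein, heat shock, p53 and BCL2 family lists gave the same counts adjusted over the list alone.

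Of 25 genes of Src kinases and immune receptor signalling, 12 rose and 6 fell, with a median of 0.24 (adjusted p = 0.0122, adjusted p = 0.393 with an estimated correlation). TYROBP, an adaptor of immune receptors, rose by 3.68, and the list did not pass without both arrays labelled shRNA 2 (adjusted p = 0.145) or after normexp (adjusted p = 0.101, median 0.48). Of 24 integrin and adhesion genes, 17 rose and 4 fell, with a median of 0.78 (adjusted p = 0.000224, adjusted p = 0.186 with an estimated correlation), and ITGB2, the common chain of leukocyte integrins, rose by 2.09. Of 21 immune checkpoint genes, 8 rose and 5 fell (adjusted p = 0.220), and PDCD1, which encodes the receptor PD-1, rose. Of 12 MHC class II genes, 2 rose and 6 fell (adjusted p = 0.389), or 3 and 7 adjusted over the list alone, with HLA-DOA among those that fell. With shRNA 1 the class II list had 6 genes higher and 3 lower (median 0.20, adjusted p = 0.434), and on the arrays labelled shRNA 2 it had 1 higher and 8 lower (median -0.71, adjusted p = 0.0293, adjusted p = 0.272 with an estimated correlation). Of 13 MHC class I genes, 5 rose and 2 fell (adjusted p = 0.220). Of 28 interferon response genes, 11 rose, IFIT2 among them, and 10 fell (adjusted p = 0.587). Of 13 genes of the small RNA machinery, 2 rose and 6 fell (adjusted p = 0.587), AGO4 among the first and DICER1 among the second. The Src, integrin, checkpoint, MHC class I, interferon and small RNA lists gave the same counts adjusted over the list alone. In all, 16 of 40 lists passed, 15 higher and 1 lower, 36 passed with fry, and 0 passed with an estimated correlation. For immediate early genes the estimated correlation was -0.0085, under the preset 0.01, yet camera's unadjusted p rose from 3.39e-12 to 0.00473. The lost calls thus also reflect the 3 degrees of freedom, and do not measure correlation between genes alone. Fry asks only whether a list moved, and 55.9% of all genes changed. Other lists whose call differed between the groups, with shRNA 1 and then shRNA 2 against scramble, were ERK output (adjusted p = 0.0504 and 0.00734), FOXO targets (0.0499 and 0.461), G1/S (0.0481 and 0.124), cholesterol synthesis (0.235 and 0.0114), p53 targets (0.283 and 0.0284) and Src kinases (0.109 and 0.000857), and none of these calls held with an estimated correlation (adjusted p of 0.272 or more).

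**Figure D4:**
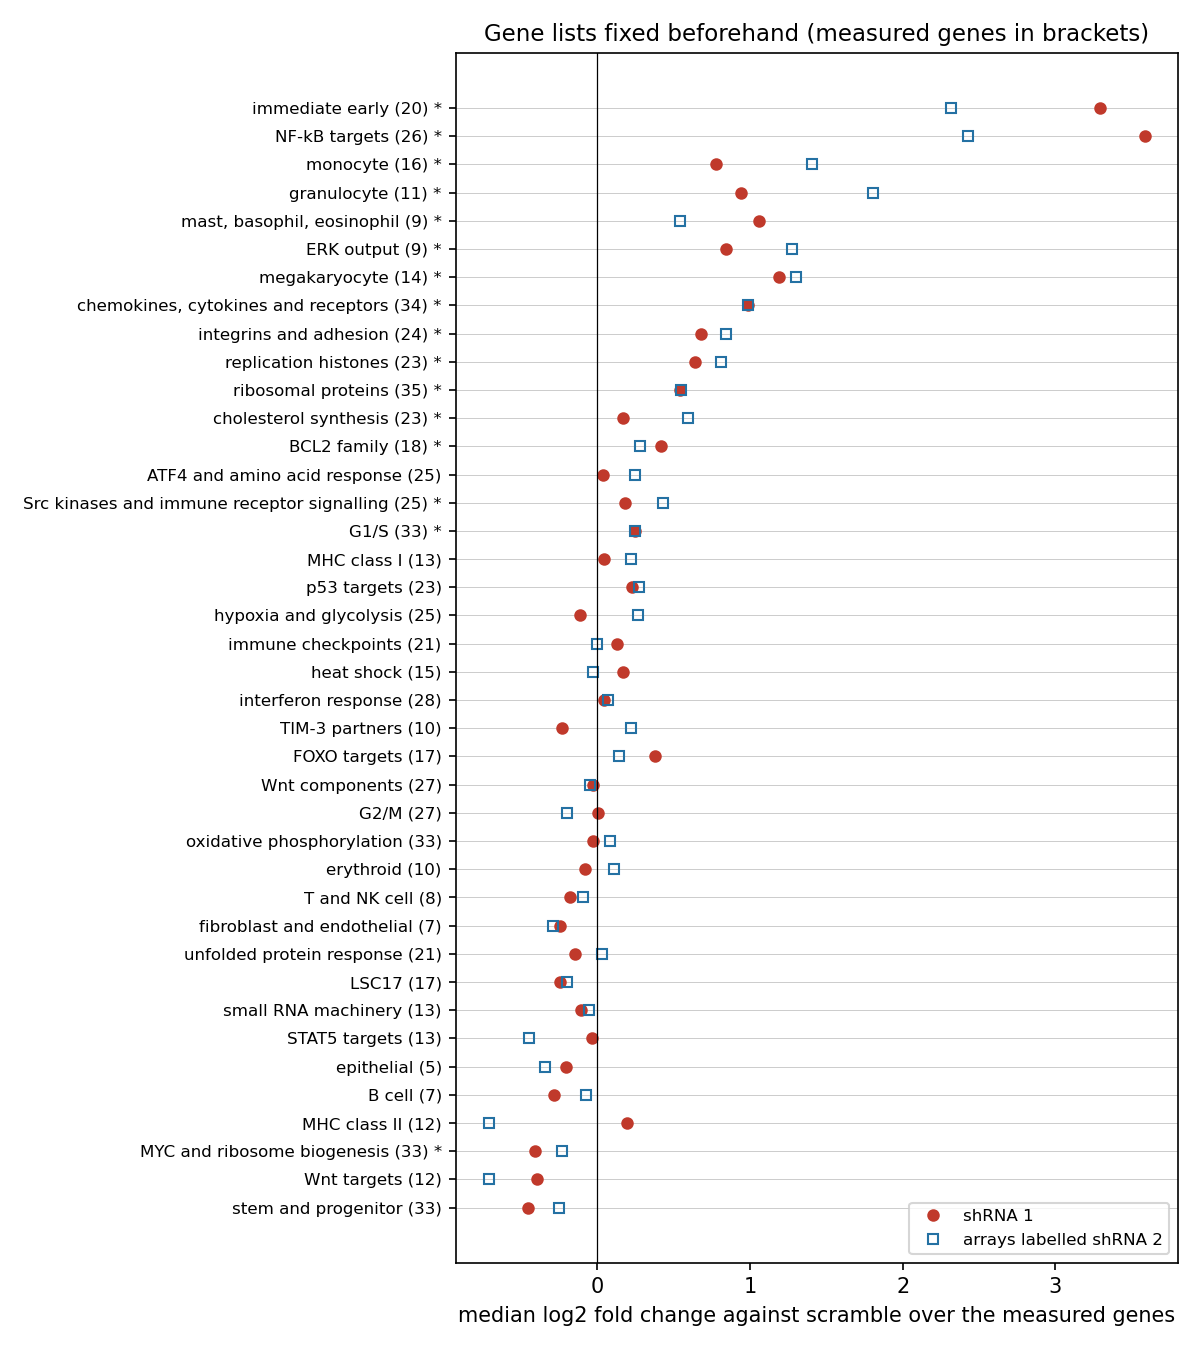
Median log2 fold change against scramble over the measured genes of each list, for shRNA 1 (filled) and the arrays labelled shRNA 2 (open), with the number of measured genes in brackets. An asterisk marks the 16 lists that passed in the shRNA mean, all at a preset correlation, with NF-kB targets and immediate early genes farthest to the right.

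Set against each other, the shRNA groups differed in many single genes. Of 34 chemokine, cytokine and receptor genes 9 were higher and 15 lower on the arrays labelled shRNA 2, and of 10 erythroid genes 5 were higher and 1 lower, and neither list passed camera (adjusted p = 0.105 and 0.256). Of 28 interferon response genes 3 were higher and 6 lower, with a median of 0.016, and the list did not pass camera (adjusted p = 0.998). Fry, which passed 30 of the 40 lists in this contrast, called it in the lower direction (adjusted p = 0.00898). Fry also passed the chemokine and erythroid lists (adjusted p = 0.000416 and 0.00173). HBG1, which encodes a fetal globin, was 4.85 ± 0.42 higher on the log2 scale (adjusted p = 0.00293), and VSIG4, a macrophage receptor, was 3.88 ± 0.15 higher (adjusted p = 0.000979). The signalling gene PLEKHG1 was at least 2.75-fold higher, the gluconeogenic enzyme gene FBP1 at least 2.75-fold, PKIB at least 3.27-fold, and the transcription factor gene LHX6 was 2.87 ± 0.07 higher. GABBR2 was 23.1-fold lower (-4.53 ± 0.07, adjusted p = 0.000794) and CXCL10 lower by 10.3-fold (-3.37 ± 0.27). CXCL11 was at least 6.84-fold lower, TTC39A at least 4.45-fold, FCGR3A, an antibody receptor gene, at least 3.85-fold, and TEX14 at least 2.93-fold. In total 6385 genes differed, 3190 higher and 3195 lower, 1188 of them by 2-fold or more. Without 1 array the count fell to 3077 (shRNA 1 replicate 1), 3313 (shRNA 1 replicate 2) and 4018 (shRNA 2 replicate 2), and after normexp it was 3907. CXCL11 did not pass without either shRNA 1 array (adjusted p = 0.0630 and 0.0602), nor did TEX14 and FCGR3A after normexp (adjusted p = 0.0630 and 0.172).

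Of 26 NF-kB targets, 21 were lower on the arrays labelled shRNA 2 than on the shRNA 1 arrays and 2 were higher, with a median of -0.73, or -0.72 with dim genes at their bound (adjusted p = 3.84e-08, adjusted p = 0.281 with an estimated correlation). Of 20 immediate early genes, 15 were lower and 1 higher, with a median of -0.84 (adjusted p = 2.59e-06, adjusted p = 0.281 with an estimated correlation). Of 12 MHC class II genes, 10 were lower and 1 higher (median -0.63, adjusted p = 0.00149, adjusted p = 0.281 with an estimated correlation). Of the 10 TIM-3 partners, HAVCR2 included, 8 were higher and 0 lower (median 0.45, or 0.29 after normexp, adjusted p = 0.00145, adjusted p = 0.281 with an estimated correlation). Of 25 genes of Src kinases and immune receptor signalling, 15 were higher and 2 lower (median 0.36, adjusted p = 0.00787), and of 13 STAT5 targets 1 was higher and 8 lower (median -0.35, adjusted p = 0.00787). These lists gave adjusted p = 0.339 with an estimated correlation. Of 11 granulocyte genes 7 were higher and 2 lower (median 0.76, adjusted p = 0.0163, and 0.0643 over probes well above background on all 6 arrays), and of 24 integrin and adhesion genes 9 were higher and 2 lower (median 0.21, adjusted p = 0.0151), each with adjusted p = 0.339 with an estimated correlation.

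Another 6 lists passed in this contrast, each with adjusted p = 0.339 with an estimated correlation, and each call ended without 1 array. Stem and progenitor genes were 15 higher and 4 lower (median 0.26, adjusted p = 0.0322, at most 0.0855 without 1 array), monocyte genes 7 and 2 (median 0.71, or 0.64 with dim genes at their bound and 0.30 after normexp, adjusted p = 0.0339, at most 0.0642), and T and NK cell genes 4 and 0 (median 0.44, adjusted p = 0.0339, at most 0.0642). Genes of MYC and ribosome biogenesis were 10 higher and 1 lower (median 0.12, adjusted p = 0.0357, at most 0.0743), hypoxia and glycolysis genes 12 and 4 (median 0.38, or 0.19 after normexp, adjusted p = 0.0322, at most 0.0743), and heat shock genes 1 higher and 6 lower (median -0.33, adjusted p = 0.0163, at most 0.0743). Adjusted over the list alone the counts were 22 lower and 2 higher for NF-kB targets, 16 and 3 higher and lower for Src kinases, 3 and 9 for STAT5 targets, 8 and 2 for granulocyte genes, 10 and 2 for integrins, 17 and 4 for stem and progenitor genes, 8 and 2 for monocyte genes, 14 and 5 for hypoxia and glycolysis genes and 1 and 7 for heat shock genes, and the same as above for the other 5 lists. After normexp the MYC and hypoxia lists did not pass (adjusted p = 0.158 and 0.0977), over probes well above background on all 6 arrays the monocyte, MYC and T and NK cell lists did not (0.193, 0.0643 and 0.0531), on ranks the T and NK cell list did not (0.0510), and with the mean of a gene's kept probes the stem and heat shock lists did not (0.0548 and 0.0643). The other 26 of the 40 lists did not pass.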

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

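The tests of the HAVCR2 level, of the RNA on the arrays labelled shRNA 2, of quantile normalization, of other probes, of respiratory chain genes and of admixed cells were chosen after the results were seen, and the brightness tests before. The genes and lists of this paragraph and the next stood out because the difference between shRNA 2 and shRNA 1 was itself tested and passed, and the later patterns were weighed because they ran across both shRNA groups. HAVCR2 was 1.79 higher on the arrays labelled shRNA 2, and 6385 genes differed. Among the genes with the highest or lowest shRNA means the log2 differences were -0.72 for IL1B, 2.28 for HBB, -1.99 for CXCL1, -3.17 for CCL4, 1.61 for MPO, -1.71 for CCL1, -1.77 for WFDC21P, -4.53 for GABBR2, 0.85 for PLD2, 1.59 for UTP14A and 0.76 for HSDL2. Among the genes named for this contrast they were 4.85 for HBG1, 3.88 for VSIG4, 3.71 for PLEKHG1, 3.38 for FBP1, 3.22 for PKIB, 2.87 for LHX6, -4.03 for CXCL11, -3.85 for TTC39A, -3.80 for TEX14, -3.70 for FCGR3A and -3.37 for CXCL10. For the genes whose dimmer group was not above background these are fitted values and only bounds hold, at least 2.75-fold for PLEKHG1, 2.75-fold for FBP1, 3.27-fold for PKIB, 6.84-fold for CXCL11, 4.45-fold for TTC39A, 2.93-fold for TEX14 and 3.85-fold for FCGR3A. Among TIM-3 partners they were 0.60 for PLCG2, 0.61 for LGALS9, 0.49 for CTNND1, 0.26 for CEACAM1, 0.36 for LYN and 0.41 for LCP2. Of 136 list members that the naming rule took by their p in the shRNA mean, 87 differed, against 36.8% of all 17367 genes. A small p in 1 contrast favours a small p in another of the same fit, so the share of all genes is not a fair baseline.

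Medians of the lists that differed were 0.45 for TIM-3 partners, -0.73 for NF-kB targets, -0.35 for STAT5 targets, 0.26 for stem and progenitor genes, 0.71 for monocyte genes, 0.76 for granulocyte genes and 0.44 for T and NK cell genes. They were -0.63 for MHC class II, 0.12 for MYC and ribosome biogenesis, 0.38 for hypoxia and glycolysis, -0.33 for heat shock, -0.84 for immediate early genes, 0.36 for Src kinases and immune receptor signalling and 0.21 for integrins and adhesion. No list held with an estimated correlation.

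As many as 9248 genes changed on the arrays labelled shRNA 2 although HAVCR2 was not lower there. If the level of the HAVCR2 transcript had set the size of the changes, shRNA 2 would have moved other genes as it moved HAVCR2. The change of HAVCR2 was -0.12 of that with shRNA 1. The slope of the shRNA 2 on the shRNA 1 fold changes was instead 0.744, or 0.733 with no correction. For 0.744 the covariance from shared controls was taken off, and the mean squared SE was taken off the variance of the shRNA 1 fold changes. Brighter scramble arrays and the scaling were not the whole source, since of the 2339 genes called at 2-fold or more 97.3% still passed in the same direction after quantile normalization and 90.6% also stayed at 2-fold or more. The same RNA as on the scramble arrays was argued against for the arrays labelled shRNA 2 by an SD of 0.863 between these groups, against at most 0.369 between replicate arrays. Replicate arrays may be technical, so this SD cannot exclude another preparation of scramble cells, and a mix of RNA was not tested. A loss of TIM-3 protein without loss of the transcript, a difference in culture or handling of the scramble cells, the position on the slide and a wrong label from outside the series stay open and may each add to the shared part.

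Ribosomal protein genes and replication histone genes rose together with both shRNAs. For the histones a scaling error for bright probes was argued against, since unlisted genes of the same brightness had a median of 0.037 against 0.75 for the list. For the ribosomal proteins it cannot be told apart from a change in the cells. There the matched genes had a median of 0.35, under the list's lower quartile of 0.44, but they were dimmer than the list by 0.83 on the log2 scale, so the bound written beforehand was not a fair one, and quantile normalization left the list a median of 0.16. The choice of the brightest probe was not the whole source, with a median of 0.46 over 29 other probes, of which 19 were higher and 4 lower past the threshold. The 4 lower probes were among the dimmer ones, with mean log2 signals of at most 2.67, though dim probes also rose, such as 1 of RPL5 (signal 0.06, log2 fold change 0.47). Better labelling of short abundant transcripts was to raise the respiratory chain genes as well, and their median was -0.029 (SD 0.29). Their brightness and length were not set against those of the ribosomal proteins, so this test cannot decide the question.

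Of 104 markers of mature blood cells on the array, 37 rose in the shRNA mean, while 12 fell and 44 were not well above background in any group. Red cells mixed into the cultures were argued against by the alpha-globin gene HBA2, which was well above background on 0 shRNA arrays against 4 for HBB. They were not excluded, since nothing here shows that the 3 HBA2 probes can detect the transcript. Of 13 abundant monocyte and neutrophil genes, 3 rose, S100A8 and MPO among them, and 7 were well above background on any shRNA array. Most of them were to rise if monocytes or neutrophils had been mixed into the cultures, and most did not. The set pools genes of several cell types and stages, so no 1 admixed cell type need raise most of it. The count therefore cannot tell whether such cells were present. CD14 fell, while the fall of S100A9 did not hold after quantile normalization (adjusted p = 0.0906) or without scramble replicate 1 (adjusted p = 0.171), among other settings, and is not counted here. No biological explanation was tested for this pattern.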

How the results depend on the processing

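The depth of these data is the signal over background, which left most spots of each array not well above it, so fold changes of dim genes are bounds and moved most with the background correction. The normexp correction on the median signal, the percentile over all probes and the fit without both arrays labelled shRNA 2 were chosen after the data were seen. The normexp correction on the mean signal column was not run because the files lack that column, and a block for slide or scan was not run because there was 1 of each. Leaving out 1 array leaves its group with 1, which is assumed to vary like the others.

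HAVCR2 kept its direction in the shRNA mean under every alternative, and its call under all but 2. After normexp it was -0.15 (adjusted p = 0.173), and with the 4 shRNA arrays as 1 group it was -0.71 with adjusted p = 0.444, where the difference between the shRNAs counts as spread by construction. With the replicate block its adjusted p was 0.00708. Without 1 array it lay between -0.81 and -0.61.

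Over all non-control probes, where more genes are tested, 5742 genes changed in the shRNA mean, 4750 with shRNA 1 and 5057 with shRNA 2, 1168 differed between the shRNAs, 2694 changed the same way with each, and the correlation was 0.757. With the 4 shRNA arrays as 1 group 5098 genes changed. After normexp 3907 genes differed between the shRNAs and the correlation was 0.799, and the cause was not tested. The correlation was 0.762 after quantile normalization and 0.767 over probes well above background on all 6 arrays. Stricter thresholds give fewer genes by construction. At an adjusted p under 0.01 the counts were 6175 for the shRNA mean, 5609 for shRNA 1, 5662 for shRNA 2, 2809 for the difference and 3485 the same way. At 2-fold or more they were 2339, 2622, 2548, 1188 and 1447.

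Leaving out 1 array in turn gave 7059 to 9085 genes for the shRNA mean, 6465 to 8989 for shRNA 1, 6939 to 8347 for shRNA 2, 3077 to 5757 for the difference between the shRNAs, 4453 to 5247 changed the same way, and a correlation of 0.752 to 0.780. The difference fell to 3077 and 3313 genes without either shRNA 1 array and to 4018 without shRNA 2 replicate 2.

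Of the gene lists, 0 passed with an estimated correlation in the shRNA mean and 0 in the difference between the shRNAs, against 36 and 30 with fry. Of the 16 lists called in the shRNA mean, 14 kept their call with the replicate block, 14 after quantile normalization, 14 with the percentile over all probes, 13 with camera on ranks, 12 over probes well above background on all 6 arrays (where 37 lists could be tested, without the mast cell, basophil and eosinophil list), 10 after normexp and 11 without both arrays labelled shRNA 2. The replicate block ended the calls of G1/S and of cholesterol synthesis (adjusted p = 0.0546 for each). Of the 14 lists called in the difference, 14 kept their call with the replicate block, after quantile normalization and with the percentile over all probes, 13 on ranks, 12 after normexp, 12 with the mean of a gene's kept probes and 10 over probes well above background on all 6 arrays. Without 1 array 14 to 16 lists passed in the shRNA mean and 10 to 13 in the difference. G1/S and cholesterol synthesis were the lists whose calls in the mean of both shRNAs ended without 1 array, with adjusted p up to 0.102 and 0.0680.

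Some named genes changed direction, and the cause was not tested beyond what the setting shows. With the mean of a gene's kept probes CEACAM1 was -0.11 and BCL2A1 2.66, since their probes differ. After normexp LCP2 was 0.058 and S100A9 0.14. Without both arrays labelled shRNA 2, CTNND1 was -0.087 and CEACAM1 -0.00028. HAVCR1 lay between -0.056 and 0.31 when 1 array was left out. Among the other results for named genes over all settings, 1945 kept their side of the threshold and direction, 29 lost and 16 gained a call.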
